A study of Mus musculus with 8 samples.

How the data were processed

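RNA from mouse embryonic stem cells of a 129X1 x 129S1 background was measured on 8 Affymetrix expression arrays, each hybridised with biotin-labelled RNA. A knockdown line, carrying a short hairpin against either Top1 or p53, was combined with mock cells at 1:4. In the cocultures the cells shared a dish for 4 days, and in the mixes the cells were grown apart for 4 days and their RNA was pooled at the same ratio. The 4 groups (shTop1 mix, shTop1 coculture, shp53 mix and shp53 coculture) held 2 arrays each, which the labels call biological replicates. The labels do not say whether the replicates came from separate thaws or passages, or whether the mixes shared mock RNA, so the p-values measure the spread between these samples.

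The deposited values are linear signal intensities, 1 per probe set and array, and the tool that made them is not given in the sources used here. On every array the mean of the values without the highest and lowest 2% was about 500.003, so the deposited intensities had been scaled by the authors to a common trimmed mean, as read from the values. The share of values under the pseudocount of 16 was 21.1% to 25.6% per array, and the number of arrays limits the precision.

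Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation used here, 932 had several and 9211 were not listed. Symbols were updated through gene identifiers, and only probe sets with 1 symbol were named, giving 18194 genes. The intensities were quantile normalized and taken as log2(value + 16), so fold changes of low genes are understated. Each gene was represented by its probe set with the highest mean. Genes were kept where that mean reached the 30th percentile of all probe sets, a signal of 22.1, which left 14267 genes. A probe set named for the p53 gene itself was not analysed here.

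Group means were fitted over all 8 arrays with limma 3.58.1 (lmFit and eBayes without a trend, R 4.3.3), leaving 4 residual degrees of freedom. P-values were two-sided and Benjamini-Hochberg adjusted with a threshold of 0.05. The comparisons were coculture against mix in each knockdown, their mean, their difference, and shTop1 against shp53 in the mixes and in the cocultures. A set of 30 gene lists with 601 members was fixed before the data were examined, of which 553 were named and 515 tested. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 30 lists. The lists were p53 targets, mTOR pathway, glycolysis, hypoxia, amino acid response, ER chaperones, heat shock, cholesterol synthesis, pluripotency, primed epiblast, primitive endoderm, primitive streak and mesoderm, neural, trophectoderm, 2-cell-like, fibroblast, G1/S, G2/M, apoptosis, interferon and MHC, Myc and ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, Nodal and BMP, Wnt, FGF-ERK and immediate early, lysosome and autophagy, oxidative stress, imprinted, and Hippo. A list of snoRNA host genes was added after the data were seen.

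Genes were named by a rule fixed before the data were examined. Since no comparison had 5 genes past the threshold, the 5 with the smallest p were named, together with Top1 and, per list, the 2 members with the smallest p. Members that passed when adjusted over their list alone, and genes called with trended variances, were named after their values were seen.

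The steps were tested on simulated data with known changes. In the mean coculture comparison of 14267 genes, the gene test recovered 27.9% of genes changed by 0.5 on the log2 scale, 68.2% of those changed by 1 and 87.9% of those changed by 2, with 9 false calls. With a single knockdown it recovered 1.5% (shTop1) and 5.9% (shp53) of genes changed by 0.5, and 36.4% and 39.4% of those changed by 1, with 5 and 3 false calls. The list test recovered 5 of 5 lists shifted by 0.25 and called 0 of 22 unchanged lists. In the real data the estimated inter-gene correlation reached 0.21 (glycolysis), against the preset 0.01. The 0 of 22 therefore describes the simulated data and is not a rate of false calls for the real lists.

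Alternatives planned before the data were examined were a replicate block, median centring, no filter and a stricter one, the mean of a gene's probe sets, every probe set by itself, trended and robust variances, only the groups compared, pseudocounts of 1 and 64, leaving out each array, an estimated inter-gene correlation, and the rotation test fry. The authors' scaling alone, a covariate for the Actb 3'/5' ratio and a covariate for the mean signal of each array were added after the data were seen.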

Results

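Expression was measured on 8 arrays of mouse embryonic stem cell RNA, 2 in each of 4 groups. The design set cocultures of knockdown and mock cells against RNA mixed from the same cells grown apart, so that changes from cells living together could be told from the knockdowns' own effects. Mean signal ranged from 812 to 896 per array. On the first principal component, which held 19.9% of the variance, the mixes lay between -21.1 and -5.14 and the cocultures between -2.94 and 26.1. The next component, with 16.9%, set shTop1 coculture replicate 1 (32.6) apart from the other arrays (-15.5 to 3.63), and this array also had the highest mean signal. The 3'/5' ratio of Actb, a sign of RNA integrity, differed between cocultures and mixes by 0.009 on the log2 scale (SD 0.0859 and 0.0880, n = 4 each, two-sided exact permutation p = 0.857).

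Top1, the DNA topoisomerase that one hairpin targets, had a signal of 5213 ± 146 in the shTop1 mix, 5282 ± 1.35 in the shTop1 coculture, 5569 ± 160 in the shp53 mix and 5729 ± 222 in the shp53 coculture (SD, n = 2 each). Knockdown RNA made up 20% of each mix, which limits how far the level can fall there, and its share in the cocultures after 4 days was not measured. Over both conditions Top1 was lower in the shTop1 samples by a log2 difference of -0.11, a ratio of 0.929 (n = 4 each, two-sided exact permutation p = 0.0286, the smallest this design allows). Of the 2 other Top1 probe sets, which are far dimmer, one had a log2 difference of 0.15 (SD 0.312 and 0.392, n = 4 each, exact permutation p = 0.571). The other had mean log2 signals of 5.50 with shTop1 and 5.11 with shp53, around the filter of 5.25, so its difference is not given. The mean of the 3 probe sets, which weighs these dim ones like the bright one, was above 0 and says little about the knockdown. The p53 gene's own level was not analysed here.

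Averaged over both knockdowns, genes of the primed epiblast, the state that follows naive pluripotency, were lower in coculture than in the mixes, with a median log2 change of -0.36 and all 10 tested members below 0 (camera adjusted p = 1.4e-07, and adjusted p = 0.375 with an estimated correlation). Of these, 4 fell when adjusted over the list alone. Fgf5, a growth factor of the early epiblast, fell to 0.499 times the mixes, as signal plus the pseudocount of 16 and averaged over both knockdowns. The others, by log2 changes, were the transcription factors Pou3f1 (-0.47) and Sox3 (-0.29), and the Wnt effector Lef1 (-0.43). Over all genes 0 of the 10 passed. The signal of Fgf5 was 108 ± 15.6 in the shTop1 mix against 24.3 ± 2.49 in its coculture, and 99.9 ± 27.1 in the shp53 mix against 71.5 ± 6.79 in its coculture (SD, n = 2 each). The shTop1 coculture value lies close to the low-signal filter of 22.1.

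The FGF-ERK and immediate early list was also lower in coculture, with a median of -0.27 and 13 of 15 members below 0 (camera adjusted p = 0.0020, and adjusted p = 0.375 with an estimated correlation). The call was lost with fry (adjusted p = 0.0765), and leaving out 1 array the median ranged from -0.28 to -0.18. In all, 3 members fell and 2 rose adjusted over the list alone, and over all genes 0 passed. Those that fell were the feedback inhibitors of receptor tyrosine kinase signalling Spred1 (-0.36) and Spry4 (-0.83), and the AP-1 subunit Fosl1 (-0.99). Those that rose were the AP-1 subunit Fos (0.50) and the early response gene Ier3 (0.35). With trended and robust variances Fos, which goes against its list, was the only member called over all genes (limma adjusted p = 0.0496). The Wnt list had a median of -0.18 (camera adjusted p = 0.035, and adjusted p = 0.375 with an estimated correlation). It had -0.24 with shTop1, with 7 of 8 members below 0, but -0.042 with shp53, with 4 of 8 below 0 (camera adjusted p = 0.590), and the difference was not called (camera adjusted p = 0.612). Ccnd1, which encodes cyclin D1 (-0.30), and Lef1 fell adjusted over the list alone, and over all genes 0 of 8 passed. The Wnt call was lost without shp53 mix replicate 1 or shTop1 coculture replicate 1, with adjusted p up to 0.0966, in 5 of 11 other settings and with fry (adjusted p = 0.0576). Its median was -0.043 without a filter and with every probe set by itself, -0.11 with the mean of all probe sets, and -0.33 to -0.16 leaving out 1 array.

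Genes induced by low oxygen were higher in coculture, with a median of 0.26 and 17 of 20 members above 0 (camera adjusted p = 0.00011, and adjusted p = 0.375 with an estimated correlation). Adjusted over the list alone 5 members rose and over all genes 0 passed. They were the transcriptional repressor Bhlhe40 (0.40), Ndrg1 (0.51), the glycolytic regulator Pfkfb3 (0.52), the oxygen sensor Egln3 (0.44) and the mitophagy receptor Bnip3 (0.25). Bhlhe40 had a signal of 1730 ± 61.1 in the shTop1 mix and 2389 ± 114 in its coculture, and 1843 ± 36.9 and 2343 ± 154 in the shp53 samples (SD, n = 2 each). Glycolysis genes had a median of 0.14, with 13 of 13 members above 0 (camera adjusted p = 0.0083, and adjusted p = 0.451 with an estimated correlation). No member passed over the list alone or over all genes, and the smallest p belonged to the phosphofructokinase gene Pfkl (0.25 ± 0.08, SE) and the hexokinase gene Hk1 (0.30 ± 0.13, SE, and 0.18 to 0.42 leaving out 1 array).

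Lysosome and autophagy genes were higher in coculture, with a median of 0.15 and 17 of 20 members above 0 (camera adjusted p = 0.0020, and adjusted p = 0.375 with an estimated correlation). A single member rose adjusted over the list alone, Hexa, a subunit of the lysosomal enzyme beta-hexosaminidase (0.35), and over all genes 0 passed. The call was lost with the mean of all probe sets of a gene, where the median was 0.075 (adjusted p = 0.0724). The autophagy receptor Sqstm1 had a value of 0.28 ± 0.08 (SE). Cholesterol synthesis genes had a median of 0.12, with 15 of 17 above 0 (camera adjusted p = 0.019, and adjusted p = 0.429 with an estimated correlation), and 0 members passed over the list alone or over all genes. Stard4, a sterol carrier, had a value of 0.22 ± 0.07 and Fdft1, squalene synthase, 0.20 ± 0.07 (SE). The cholesterol call was lost without shTop1 mix replicate 1, shTop1 coculture replicate 2 or shp53 coculture replicate 1, with adjusted p up to 0.112, and also with the mean of all probe sets (adjusted p = 0.0724) and with fry (adjusted p = 0.0693). The Myc and ribosome biogenesis list had a median of -0.11 with 16 of 21 members below 0 (camera adjusted p = 0.0072, and adjusted p = 0.429 with an estimated correlation), and 0 members passed over the list alone or over all genes. Myc, the growth-promoting transcription factor, had a value of -0.82 ± 0.31 and Nop58, a nucleolar protein gene, -0.22 ± 0.09 (SE). The list's median was -0.067 without shTop1 mix replicate 2 and -0.18 without shp53 coculture replicate 2, and the Myc gene had -0.47 without shp53 coculture replicate 1 and -1.18 without shp53 coculture replicate 2. The list's call was lost with median centring and with the authors' scaling alone (medians -0.056 and -0.11, adjusted p = 0.172 and 0.103), and with fry (adjusted p = 0.132).

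**Figure D1:**
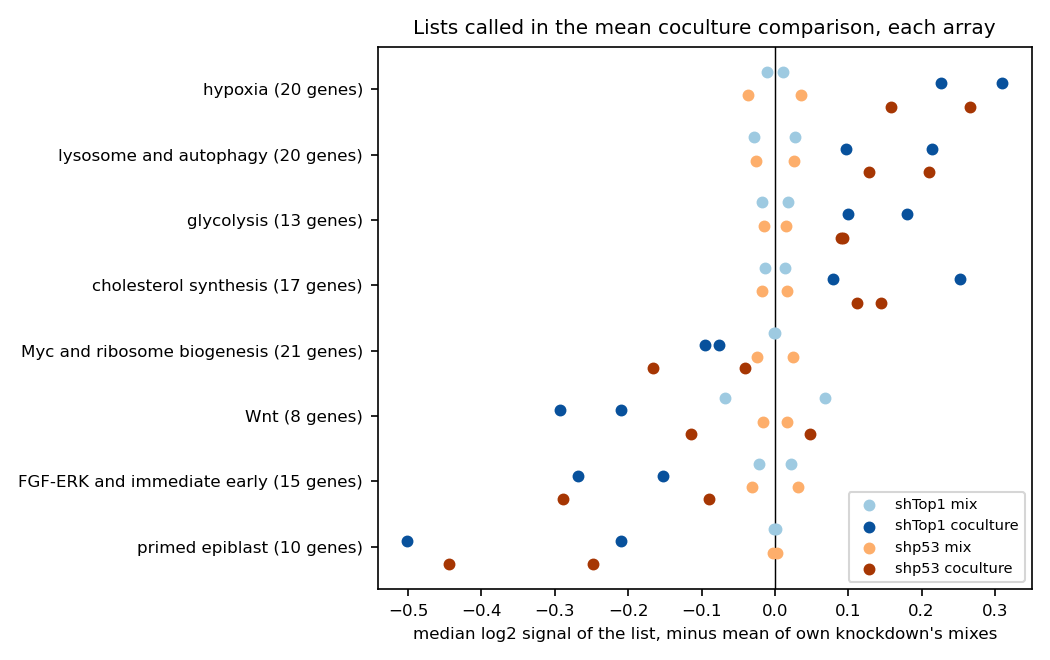
Each point is 1 array, placed by the median log2 signal of a list's tested genes minus the mean of its own knockdown's mixes, for the 8 lists called in the mean coculture comparison. The hypoxia list lies above 0 on all 4 coculture arrays, the lowest at 0.159.

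**Figure D2:**
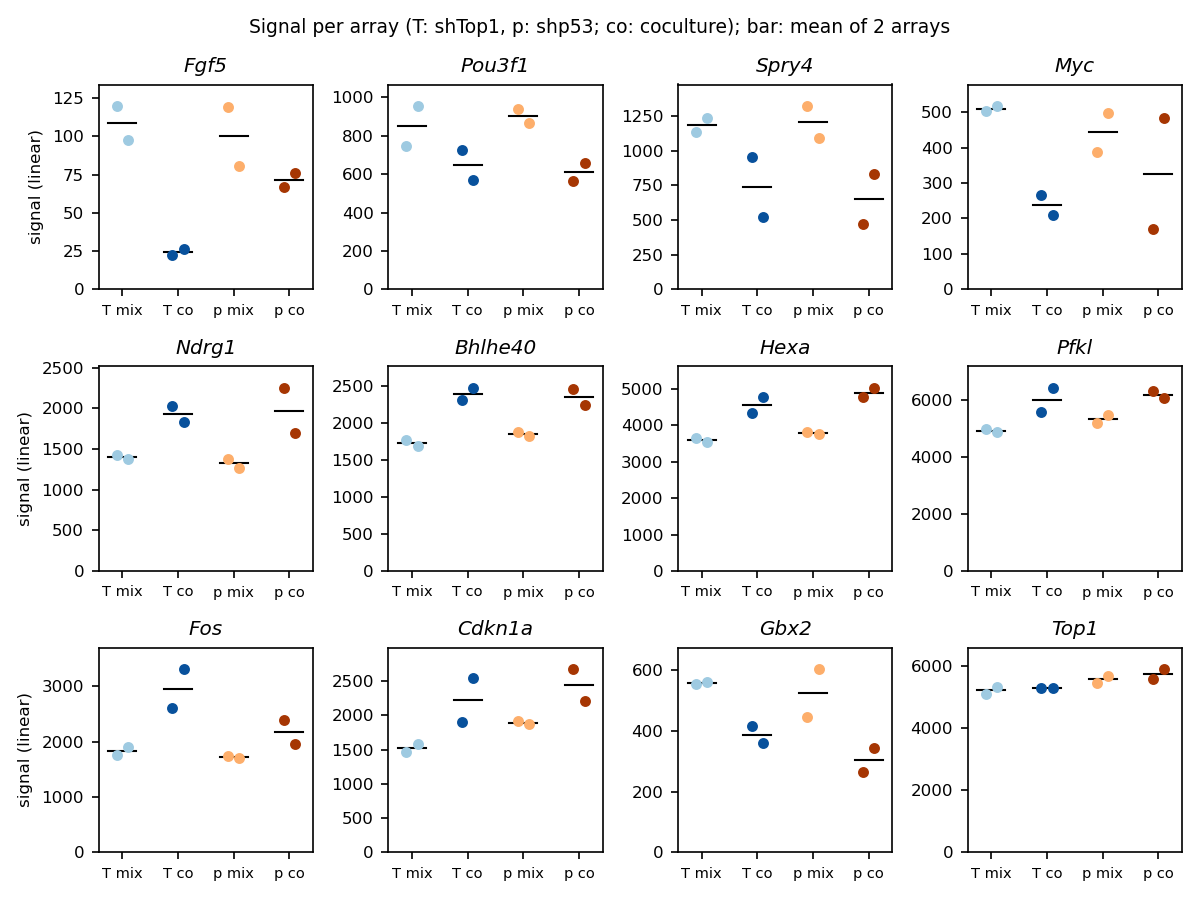
Linear signal of 12 genes on each of the 8 arrays, with bars for the mean of the 2 arrays of a group and every axis starting at 0. Fgf5 has a mean of 24.3 in the shTop1 coculture against 108 in the shTop1 mix.

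At the level of single genes, 0 of 14267 genes passed limma's test in the mean coculture comparison, and the smallest adjusted p was 0.279. At an unadjusted p under 0.05 there were 1672 genes, 1012 higher and 660 lower in coculture. By chance 713 are expected, with a wider spread where genes are not independent. In a fit of 2 groups the real split gave 1935 such genes and the other 34 splits of the arrays up to 1733. The split with 1733 exchanged only shp53 mix replicate 2 with shTop1 coculture replicate 1, so it keeps part of the coculture difference. Other splits that exchanged 1 mix with 1 coculture keep part of it too but gave 505 to 1063. Splits with 2 mixes and 2 cocultures on each side gave 488 to 790. In such a split the coculture difference adds to the residual spread, which lowers the count. The 5 with the smallest p did not pass: Krt88 (1.39), Aldh3b2 (0.88), Tshb (-0.69), Pfn4 (-1.03) and Cd79a (0.86). All lay below the 17th percentile of mean signal, where the size of a change is uncertain. With trended and robust variances limma called 31 genes, 19 higher and 12 lower. Those from the fixed lists were Bhlhe40 and Ndrg1 (hypoxia), Hexa (lysosome) and Fos (FGF-ERK), all higher (limma adjusted p 0.0430 to 0.0496).

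Of the other lists in this comparison none was called, with camera adjusted p from 0.0523 to 0.894. Some were called in other settings. Primitive endoderm was called higher in 6 (adjusted p 0.026 to 0.047), G2/M under both other scalings and without shTop1 coculture replicate 1, and the p53 targets with median centring and without shp53 coculture replicate 2. With median centring ribosomal proteins (0.16) and oxidative phosphorylation (0.13) were called higher, and with every probe set by itself trophectoderm was higher (0.14) and imprinted genes lower (-0.13, camera adjusted p = 0.0015). In the setting used, primitive endoderm genes had a median of 0.11 (camera adjusted p = 0.0523), with Sparc at 0.19 and Col4a2 at 0.19. The G2/M list had a median of 0.06 (0.0681), with Top2a at 0.17 and Bub1 at 0.16. The p53 targets had a median of 0.11 (0.114), with the cell cycle inhibitor Cdkn1a at 0.44 and the DNA repair gene Xpc at 0.30. The Nodal and BMP list had a median of -0.11 (0.114), with Smad6 at 0.48 and Lefty1 at -0.27, and the pluripotency list -0.03 (0.135), with Gbx2 at -0.63 and Tet1 at -0.23. Trophectoderm genes had a median of 0.15 (0.228), with Krt8 at 0.14 and Krt18 at 0.15. The fibroblast list, markers of a cell type that can be present in stem cell cultures, had a median of 0.14 (0.295), and adjusted over the list alone Col5a1 (0.37) and Cxcl12 (0.40) rose. Leaving out 1 array, the median ranged from 0.050 to 0.16 for the p53 targets, 0.044 to 0.11 for G2/M, -0.21 to -0.075 for Nodal and BMP, -0.039 to -0.0022 for pluripotency, 0.097 to 0.17 for trophectoderm and 0.086 to 0.22 for fibroblast.

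Imprinted genes had a median of -0.03 (camera adjusted p = 0.317), with Mirg at -0.35 and Mest at -0.20. The amino acid response list had -0.01 (0.516), with Slc7a3 at -0.28 and Sesn2 at -0.40, and the Hippo list 0.003 (0.708), with Ankrd1 at 0.34 and Wwtr1 at 0.27. ER chaperones had 0.05 (0.749), with Pdia6 at 0.34 and Sdf2l1 at 0.24. The mTOR pathway had 0.05 (0.779), with Ddit4 at 0.29 and Sesn2 at -0.40. At the same adjusted p of 0.779 stood heat shock (median -0.001, Dnajb1 0.27, Chordc1 -0.18), neural (0.01, Sox1 -0.99, Msi1 0.27), G1/S (0.02, Ccnd1 -0.30, Cdc45 0.29), ribosomal proteins (0.004, Rps14 0.08, Rps24 -0.08) and oxidative phosphorylation (0.03, Cycs -0.21, Sdhb 0.15). Primitive streak and mesoderm genes had -0.11 (0.849), with Tbx6 at 0.23 and Mixl1 at 0.19. At 0.880 stood the 2-cell-like list (0.005, Sp110 -0.02, Zfp352 0.03), apoptosis (0.06, Bcl2 0.39, Cycs -0.21) and interferon and MHC (0.04, Stat2 0.34, Irf1 -0.30). Oxidative stress genes had 0.02 (0.894), with Srxn1 at -0.17 and Gsr at 0.13. The median and the camera direction differed in sign for neural, G1/S, ribosomal proteins and the 2-cell-like list. Leaving out 1 array, medians this near 0 crossed it for imprinted genes (-0.066 to 0.021), amino acid response (-0.032 to 0.0099), ER chaperones (-0.0030 to 0.062), heat shock (-0.044 to 0.016) and Hippo (-0.0028 to 0.062), among others. It also moved Sox1 (-1.45 to -0.54), Msi1 (0.11 to 0.44), Mixl1 (0.082 to 0.29), Irf1 (-0.42 to -0.18), Tbx6, Krt18, Chordc1, Srxn1, Rps14, Rps24, Sp110 and Zfp352 by more than 1.5 times. The mean and the median differed in sign for heat shock, primitive streak and mesoderm, neural, G1/S and ribosomal proteins.

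With Top1-knockdown cells, camera called 7 lists between coculture and mix, 3 higher and 4 lower, and 0 lists with an estimated correlation (smallest adjusted p 0.362) or with fry. Hypoxia (median 0.25), glycolysis (0.13) and lysosome and autophagy genes (0.13) were higher. Over 12 other settings these medians ranged from 0.24 to 0.41, from 0.11 to 0.37 and from 0.053 to 0.25. Primed epiblast (-0.39), Wnt (-0.24), FGF-ERK and immediate early (-0.31) and Myc and ribosome biogenesis genes (-0.12) were lower. Adjusted over the list alone, Fgf5 (-1.62), the Wnt target Sp5 (-1.09) and the mesoderm gene Tbx6 (0.70) passed, the last from an uncalled list, and over all genes 0 members passed. Without shTop1 coculture replicate 2 the medians of primed epiblast and FGF-ERK were -0.21 and -0.15, and without shTop1 mix replicate 2 those of Wnt and Myc were -0.13 and -0.062. Only 2 lists were called without shTop1 mix replicate 2, 3 without shTop1 coculture replicate 2 and 4 without shTop1 mix replicate 1. The mean of all probe sets lost Wnt, FGF-ERK and lysosome, every probe set by itself lost Wnt and lysosome, both other scalings lost Myc (medians -0.0077 and -0.067), and a fit of only the groups compared lost glycolysis. Over all genes limma called 0 of 14267 (smallest adjusted p = 0.281), with 1170 at an unadjusted p under 0.05, 730 higher and 440 lower. Oosp3 (1.66), Aldh3b2 (1.32), Hoxa11os (1.81), Fgf5 and Hes7 (2.09) had the smallest p, all below the 22nd percentile of mean signal and so near the floor that the size of the change is uncertain. With trended and robust variances 3 were called, Rps27 (2.00), ND5 (-0.63) and Zfp936 (-0.91).

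With p53-knockdown cells, camera called 6 lists, and 0 with an estimated correlation (smallest adjusted p 0.461) or with fry. Hypoxia (median 0.23), lysosome and autophagy (0.16) and primitive endoderm genes (0.14) were higher in coculture. Primed epiblast (-0.33), FGF-ERK and immediate early (-0.23) and Myc and ribosome biogenesis genes (-0.10) were lower. Primitive endoderm lost its call without any 1 of the 4 shp53 arrays (adjusted p 0.051 to 0.182), with the mean of all probe sets (0.268) and with only the groups compared (0.0569). FGF-ERK lost its call with the mean of all probe sets, and Myc with median centring and with only the groups compared. Glycolysis (0.072, camera adjusted p = 0.0673) was not called with shp53, and cholesterol synthesis in neither knockdown alone (camera adjusted p = 0.0630 with shTop1 and 0.0673 with shp53). No member passed over the list alone or over all genes. Without shp53 coculture replicate 1 the FGF-ERK median was -0.089 and the Myc list's -0.043. Without shp53 mix replicate 2, and likewise without shp53 coculture replicate 1, 1 list was called. Over all genes limma called 0 of 14267 (smallest adjusted p = 0.270), with 979 at an unadjusted p under 0.05, 552 higher and 427 lower. Gm3363 (-1.63), Cd79a (1.45), Pfn4 (-1.48), 4933433G15Rik (-1.48) and Dennd2d (1.73) had the smallest p. All lay below the 8th percentile of mean signal, so near the floor that the size of the change is uncertain. With trended and robust variances 1 was called, Mxd3 (1.40), a member of the Mad family that opposes Myc.

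The coculture effects of the 2 knockdowns were compared gene by gene. Across 14267 genes, which are not independent replicates, Pearson's r was 0.165 and Spearman's rho 0.270, and 63.1% of genes had the same sign. Among the 7133 genes of higher mean signal r was 0.560. The real grouping gave the highest r of 18 relabellings in both sets (one-sided exact permutation p = 0.0556, the smallest possible, where the highest other r was 0.111 and 0.351). Of the genes at an unadjusted p under 0.05, 120 were higher in both, where independent lists give 28.2. Another 86 were lower in both, where independent lists give 13.2. In opposite directions there were 30 and 15. Both tests used the same variance estimate of each gene, so the counts for independent lists are only a rough guide. The comparisons share no array, though shared mock RNA is not excluded. Without shTop1 coculture replicate 2, r over all genes was 0.0639.

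**Figure D3:**
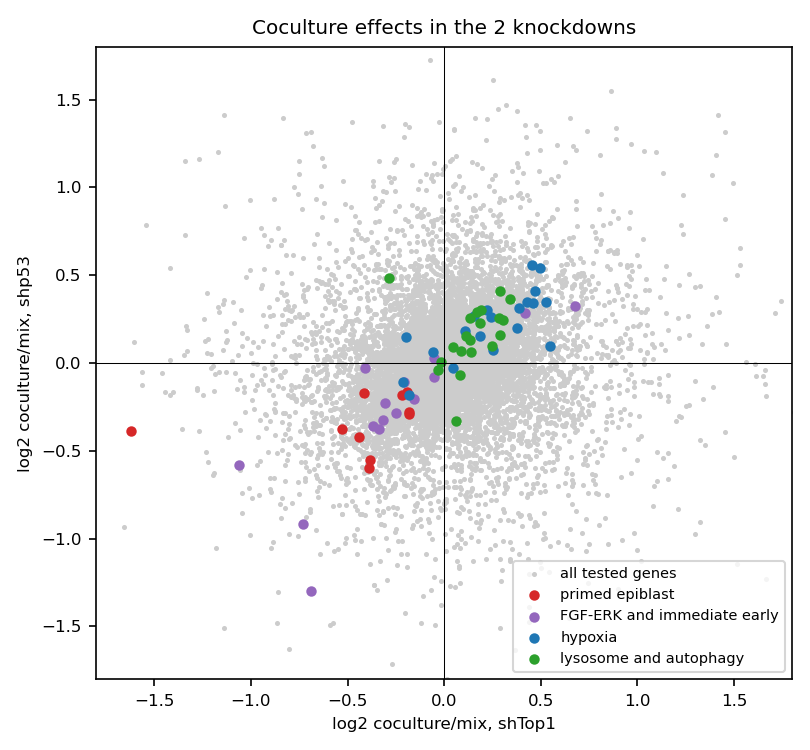
Log2 change of each tested gene between coculture and mix in the shTop1 (horizontal) and shp53 (vertical) samples, with 4 lists in colour. The axes end at 1.8 and leave out 8 genes, and the 10 primed epiblast genes lie below 0 on their mean.

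A difference between the coculture effects, shTop1 minus shp53, was called for 0 genes (limma, smallest adjusted p = 0.292, 614 at an unadjusted p under 0.05 and 0 with trended and robust variances) and 0 of the 30 lists fixed in advance (smallest camera adjusted p = 0.612). Batf, Hes7 and Gm3363 (above 0) and Dscaml1 and 1700001P01Rik (below 0) had the smallest p. Their mean signals lay at percentile 7.7 or lower, so near the floor that the sizes of these differences are not given. Adjusted over the list alone, Fgf5 (-1.23) and the interferon gene Ifih1 passed, but Ifih1 had mean signals of 10.8 and 12.8 in 2 groups, under the filter of 22.1, so its change is not given. With median centring and with the authors' scaling alone, 2 lists were called.

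Between shTop1 and shp53 in the mixes, limma called 0 genes (smallest adjusted p = 0.416, 577 at an unadjusted p under 0.05 and 0 with trended and robust variances) and camera 0 of the 30 lists. Gng7 (1.20), Frrs1l (2.03), Prtn3 (1.18), Oosp3 (-1.19) and BB283400 (-0.80) had the smallest p. All lay below the 17th percentile of mean signal, so near the floor that the size of the change is uncertain. In the cocultures limma called 0 genes (smallest adjusted p = 0.187, 682 at an unadjusted p under 0.05 and 0 with trended and robust variances) and camera 0 of the 30 lists (smallest adjusted p = 0.120). Lypd6b (-1.29), Dscaml1 (-1.55), 1700001P01Rik (-1.41), Alx4 (1.67) and Mgp (1.53) had the smallest p. All lay below the 13th percentile of mean signal, where the size of the change is likewise uncertain. Fgf5 (-1.12) passed adjusted over the list alone. With median centring 6 lists were called in the cocultures, and with the authors' scaling alone 2.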

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

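Every setting but one left the gene counts at 0: with trended and robust variances limma called 31 genes in the mean comparison, 3 with shTop1 and 1 with shp53. The causes of the moves below were not tested. Quantile normalization was the setting used, so it was not run again. The replicate numbers did not pair the samples (correlations of deviations -0.007 to 0.051); with the replicate block 0 genes and 7 lists were called in the mean comparison, without Wnt, and 7 and 6 lists with shTop1 and shp53. In the mean comparison hypoxia, primed epiblast, glycolysis and FGF-ERK kept their calls in 11 of 11 settings other than the set test. Over these settings the medians ranged from 0.22 to 0.32 for hypoxia and -0.41 to -0.22 for primed epiblast. Those of glycolysis ranged from 0.11 to 0.24 and those of FGF-ERK from -0.27 to -0.18. Leaving out 1 array, the medians were 0.22 to 0.29 for hypoxia and -0.42 to -0.28 for primed epiblast. They were 0.097 to 0.16 for glycolysis and -0.28 to -0.18 for FGF-ERK. A group of 1 array was then assumed to vary like the others.

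The mean comparison had 8 lists, 5 with the mean of all probe sets, which lost cholesterol, Wnt and lysosome (adjusted p 0.0724, 0.294 and 0.0724), and 12 with median centring, which lost Myc and gained p53 targets, primitive endoderm, G2/M, ribosomal proteins and oxidative phosphorylation. The estimated correlation called 0 lists in the mean, shTop1 and shp53 comparisons; fry called 5, 0 and 0, in the mean comparison losing cholesterol, Myc, Wnt and FGF-ERK (adjusted p 0.0576 to 0.132) and gaining primitive endoderm. With shTop1, the mean of all probe sets gave 4 lists. With shp53, every probe set by itself gave 11. For the difference, median centring and the authors' scaling each gave 2 lists; for shTop1 against shp53 in coculture they gave 6 and 2, and the stricter filter 1. Leaving out 1 array gave 2 to 9 lists with shTop1 and 1 to 6 with shp53. The correlation of the effects was 0.346 with the stricter filter, 0.276 with a pseudocount of 64, and 0.0639 to 0.199 without 1 array.

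For uncalled lists the direction given by camera changed in the mean comparison, while most medians, the values given here, kept their sign; the genes named changed sign. With median centring, heat shock had a median of 0.12, G1/S 0.11, interferon and MHC 0.044 and ribosomal proteins 0.16, the last called higher, and Rps24 had 0.12. Median centring also moved the median of all tested genes in the mean comparison from 0.022 to 0.068. With the authors' scaling alone, heat shock had 0.064, G1/S 0.057, ribosomal proteins 0.10, Rps24 0.061 and Zfp352 -0.011. Without a filter, the 2-cell-like list had 0.14 and interferon and MHC 0.0075; with the stricter filter apoptosis had 0.051. With every probe set by itself, amino acid response had -0.00066, primitive streak and mesoderm -0.078, 2-cell-like 0.092, apoptosis -0.018 and oxidative stress 0.0078. With the array mean signal covariate the 2-cell-like list had 0.12.

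With the mean of all probe sets of a gene, 2-cell-like had 0.089 and oxidative stress -0.0031, and the genes Sparc -0.0031, Sp110 0.085, Cdc45 -0.21, Top2a -0.042, Bcl2 -0.15, Rps24 0.067, Aldoc -0.017 and Wdr33 0.042. Top1, where this averages in a probe set near the filter, then had -0.065 between coculture and mix with shp53, 0.23 in the difference, and, for shTop1 against shp53, 0.034 in the mixes and 0.26 in the cocultures.

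The direction given by camera also changed for some uncalled lists without 1 array. Their medians, of which primitive streak and mesoderm crossed 0 in a fit where camera turned, had these ranges: the mTOR pathway from 0.0026 to 0.066, primitive streak and mesoderm from -0.11 to 0.050, neural from -0.085 to 0.11, 2-cell-like from -0.19 to 0.071, G1/S from 0.0059 to 0.033, apoptosis from 0.010 to 0.044, interferon and MHC from 0.00066 to 0.093, ribosomal proteins from -0.013 to 0.028 and oxidative stress from -0.016 to 0.054. The genes Sp110 and Zfp352 ranged from -0.19 to 0.15 and from -0.29 to 0.35, and Top1 from -0.0096 to 0.049 between coculture and mix with shTop1 and from -0.060 to 0.017 in the difference.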

Other observations

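In all, 27 genes outside the lists were called in the mean coculture comparison only with trended and robust variances, where limma's adjusted p ranged from 0.00267 to 0.0497, and the 5 largest changes in each direction are given here, by a rule chosen after their values were seen. Higher in coculture were Mxd3, which opposes Myc (1.02), the ribosomal protein gene Rps27 (0.99), Lactb (0.69), Klhl26 (0.56) and the protease inhibitor gene A2m (0.50). Rps27 had 2.00 with shTop1 and -0.0079 with shp53. Lower were Zfp936 (-0.71), ND5, a mitochondrially encoded subunit of complex I (-0.57), Qser1 (-0.57), Atp5md (-0.55) and the fatty acid transport gene Slc27a2 (-0.55).

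The tests of culture density, of growth and lysosome genes, of glycolysis and sterol genes and of the share of knockdown cells were chosen after the result was seen, the snoRNA host gene test was added after the data were seen, and the array mean signal test was added after the splits of the arrays had been seen.

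The 8 lists called in the mean coculture comparison were weighed against technical sources. At least 7 of the 8 kept their call and direction under each of 2 other scalings, and 7 did so with the array mean signal as a covariate, which argues against these as the whole cause. For scaling this is weak. The 2 scalings differ from each other only by a constant per array, which camera's comparison with the other genes partly cancels. With the Actb 3'/5' ratio as a covariate 8 kept theirs, but that covariate moved the effects by a median of only 0.057 of their standard error, less than the 0.1 set after the data were seen for a usable test, so RNA degradation stays open. Chance was not excluded for the number of lists. In a fit of 2 groups the real split gave 9 lists. Of the 35 splits of the 8 arrays, 2 gave as many, and the highest other gave 11. The split with 11 exchanged only shp53 mix replicate 1 with shTop1 coculture replicate 1, so it keeps part of the coculture difference. Other splits that exchanged 1 mix with 1 coculture keep part of it too but gave 0 to 7 lists, so this does not explain the 11. Limma called 0 genes in the real split, so all 35 splits gave as many (highest other 2). With trended and robust variances the real split gave 138 genes and 1 of 35 splits gave as many. The next gave 130, from exchanging shp53 mix replicate 2 with shTop1 coculture replicate 1. That split also keeps part of the coculture difference, but so do the other exchanges of 1 mix with 1 coculture, which gave 0 genes. It and the split with 11 lists set shTop1 coculture replicate 1, the array apart on the second principal component, with the mixes. The other such splits gave 2 and 3 lists. The cause of these counts was not tested. Splits with 2 mixes and 2 cocultures on each side gave 0 lists and, with trended and robust variances, 0 genes. Their residual spread holds the coculture difference, which makes calls less likely, so they are not a clean comparison.

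The cocultures may have been denser or their medium more spent than the separate cultures. The smallest shift of the hypoxia list among the 4 coculture arrays was 0.159, above 0, but density and coculture go together in this design and cannot be told apart. A larger share of knockdown cells in the shTop1 coculture is also open, since Top1 differed from the mix by 0.019, and a knockdown diluted in mock RNA leaves little room for a fall.

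Lower mTORC1 activity in coculture is a candidate explanation for part of the pattern. The Myc and ribosome biogenesis list, with a median of -0.11 (-0.18 to -0.067 leaving out 1 array), and the higher lysosome list go in the direction it predicts. Neither call held in every setting. The Myc list had -0.056 with median centring (adjusted p = 0.172, and a median of -0.0077 with shTop1). That scaling also raised the median of all tested genes, from 0.022 to 0.068 (0.030 to 0.076 with shTop1). The lysosome list had 0.075 with the mean of all probe sets (adjusted p = 0.0724). The glycolysis list, at 0.14, and the cholesterol list were higher, the opposite of what lower mTORC1 activity predicts for those genes. This does not decide the question, since the test was chosen after the result was seen. The hypoxia list was also higher in the cocultures, so another influence on the glycolysis genes cannot be told apart. The cholesterol call did not hold in every setting either. It was lost with the mean of all probe sets (adjusted p = 0.0724) and with fry (adjusted p = 0.0693). With an estimated correlation no list was called, glycolysis (camera adjusted p = 0.451) and cholesterol (0.429) included. Lower mTORC1 activity also predicts higher snoRNA host genes. The 2 members of their list with the smallest p, Snhg5 (-0.27) and Snhg3 (-0.27), were lower, though neither passed. The list had a median of -0.08, with 5 members above 0 and 7 below (limma's camera adjusted p = 0.141 as the one list in its test). The predicted rise of the list was therefore not seen in the mean comparison. Zfas1 (0.47) and 2410006H16Rik (0.41) prompted the test and were left out of the list. Both were higher with trended and robust variances (limma adjusted p = 0.0321 and 0.0430). Having prompted the test, these genes cannot count as its result. The list went against the prediction with shTop1 (median -0.20, limma's camera adjusted p = 0.0063), had 0.038 with shp53 (0.601), and was called in the difference of the coculture effects (-0.16, 0.0031, and 0.0357 with an estimated correlation) and for shTop1 against shp53 in coculture (-0.15, 0.0024).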
